A study of Mus musculus with 12 samples.

How the data were processed

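Liver RNA was measured by polyadenylated RNA sequencing in 12 libraries, 3 groups of 4 replicates: PBS, AAV with a control gRNA and AAV with a Pdx1 gRNA. The source of Cre, the gRNA sequences, the sex of the animals and any batch or date were not given in the sources used here. The values are fragment counts per gene, 1 deposited file per library, made per the file headers with featureCounts 1.4.6-p4 on paired-end alignments without regard to strand, with both ends required to map, exons summed by gene and GENCODE M13 as annotation. No normalization had been applied to these deposited counts: they were whole numbers with totals that differed between libraries. Per the submitters' processing notes, the tools were Trimmomatic 0.32, STAR 2.4.1a, featureCounts, Subread, DESeq2 1.22.0 and R 3.5.1, and the builds were GRCm38 and mm10. No authors' table of tests was used here. All 12 files listed the same 50600 genes, of which 50376 matched a symbol by gene ID in a later GENCODE release, and the rest kept their ID. Libraries differed by far more than counting error (chi-square per degree of freedom from 19.3 to 300 over all 66 pairs), so no library was a copy of another.

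Libraries held from 11824767 to 22008046 assigned counts. The 20 most abundant genes took 18.7 to 25.3% of counts after PBS, 17.5 to 21.6% after control gRNA and 17.2 to 22.5% after Pdx1 gRNA. TMM factors ran from 0.826 to 0.935, from 1.02 to 1.22 and from 0.935 to 1.19.

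Genes were filtered with filterByExpr on the group factor (minimum count 10) and scaled by TMM. All 12 libraries were fitted in 1 model with edgeR 4.0.16 (quasi-likelihood test, robust, two-sided) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05, and "rose" and "fell" are used for called genes. Log2 fold changes are given ± SE and CPM as mean ± SD over 4 libraries, with CPM computed on TMM-scaled library sizes, except for Xist and Ddx3y, whose CPM were computed on total counts. The 3 comparisons were Pdx1 gRNA against control gRNA, control gRNA against PBS and Pdx1 gRNA against PBS. Pdx1 was also tested by an exact permutation of CPM over the 70 assignments of 4 and 4 libraries. Where a group had no counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% counting interval.

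The 28 gene lists were fixed before the data were examined, as were the tests, the named-gene rule and the alternatives, except where said otherwise. Lists with at least 3 tested members (27) were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over lists). Beside it stand camera with an estimated correlation, fry, and the members called over all genes and adjusted over the list alone. Camera asks whether a list moved more than the other genes, and fry whether its genes moved one way on balance, without comparing them with other genes. Genes within 500 kb of Pdx1 were adjusted over all genes and over these genes alone.

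Named genes were Pdx1, and for Pdx1 gRNA against control gRNA and for control gRNA against PBS the 10 largest rises and the 10 largest falls (5 each for Pdx1 gRNA against PBS). These were taken among called genes with a mean of at least 1 CPM, fully separated groups and a symbol that is not a predicted-gene name. Where none passed in a direction, the 3 genes with the smallest p were taken and given as not called. The rule added up to 3 members of each list with the smallest p in each of the first 2 comparisons, the tested genes within 500 kb of Pdx1, and Ep300. Some genes that the rule names are not reported here.

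The alternatives were DESeq2 size factors, upper-quartile factors, library sizes and TMM without the 20 most abundant genes, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2 1.42.0 (Wald test), edgeR without robust estimation, limma-voom, only the 8 libraries compared, the replicate number as a block, each library left out in turn, a fold change threshold of 1.5 (glmTreat), the list tests named above, a window of 1 Mb, and the PBS libraries split into 2 and 2. After the data were seen, 3 were added: PBS libraries 2 and 3 left out (over 100 counts of the Y-linked Ddx3y), a covariate for these libraries, and smooth trends on gene length and GC content removed in each library (15192 of 15219 tested genes had a GC value). The methods were tested on simulated data with known changes. The replicate number was not used as a block because the labels do not say that it marks a shared litter, day or batch. As a check on the data, 3 of 12 pairs of libraries with the same number correlated above 0.1. Only 2 of 12 libraries correlated best with a library of their own number. Counts of the Mup, Gst, Serpina1 and Cyp families are uncertain for single members, since near-identical copies can share reads.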

Results

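Polyadenylated RNA was sequenced in 12 liver libraries from mice of the Rosa26-LSL-dCas9-p300 strain. The strain carries, at the Rosa26 locus, a fusion of nuclease-dead Cas9 to p300, a histone acetyltransferase that activates transcription, and LSL denotes a stop cassette that Cre recombinase removes. A guide RNA (gRNA) directs such a fusion to a chosen DNA site without cutting it. The design had 3 groups of 4 libraries. The first received PBS, and the others received adeno-associated virus (AAV) carrying a control gRNA or a gRNA against Pdx1, at 1e+12 viral genomes per mouse. Injection was through the tail vein at about 8 weeks of age, and livers were taken 2 weeks later. Pdx1 encodes a transcription factor of the pancreas and duodenum, so the design asks whether a silent gene can be switched on in the liver of a living animal, and what the virus and fusion change besides. Assigned counts ranged from 11824767 to 17870498 per library after PBS, from 16963079 to 22008046 after control gRNA, and from 13531769 to 18063529 after Pdx1 gRNA. Mitochondrial genes took 3.39 to 8.07% of counts after PBS, 5.11 to 7.75% after control gRNA and 3.30 to 5.72% after Pdx1 gRNA. The labels do not state that each library came from its own mouse, so p-values measure the spread between these libraries. After the filter on low counts, 15219 of 50600 annotated genes were tested.

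The PBS libraries were not of one sex pattern. PBS libraries 2 and 3 had 2.61 and 3.64 counts-per-million units (CPM) of Xist, the RNA of the inactive X chromosome, and 80.8 and 70 CPM of the Y-linked Ddx3y, both on total counts. The other 10 libraries had 692 to 1347 CPM of Xist and at most 0.187 CPM of Ddx3y, so all 8 virus libraries had the female pattern. The sex of the animals was not given in the sources used here. Leaving out these PBS libraries is an alternative chosen after the data were seen. It leaves PBS libraries 1 and 4, the pair that differed most within any group (chi-square per degree of freedom 177). A call lost in that setting can thus reflect fewer and more variable PBS libraries as well as sex.

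**Figure D1:**
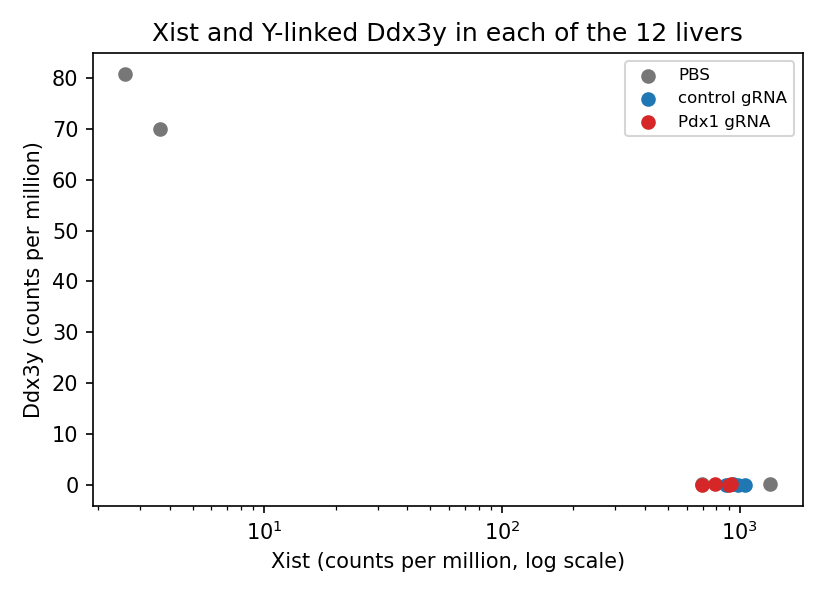
Xist (x axis, CPM on total counts, log scale) against the Y-linked gene Ddx3y (y axis, CPM on total counts) in each of the 12 liver libraries, coloured by group, 1 point per library. PBS libraries 2 and 3 lie at 80.8 and 70 CPM of Ddx3y, and the other 10 libraries lie at 0.187 CPM or below.

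The targeted gene was detected in each of the 4 liver libraries given the Pdx1 gRNA. Pdx1 (ENSMUSG00000029644.7, chromosome 5, 147269959 to 147275848, plus strand, mm10) had 26, 32, 54 and 256 counts in Pdx1 gRNA libraries 1 to 4, against 0 counts in each of the 4 PBS libraries and in 3 of the 4 control gRNA libraries. The remaining control gRNA library, number 4, had 2 counts. Mean expression was 5.20 ± 5.33 CPM (SD, n = 4) with the Pdx1 gRNA and 0.0277 ± 0.0554 CPM (SD, n = 4) with the control gRNA. The highest library, Pdx1 gRNA 4, had 13.0 CPM and the lowest had 1.35 CPM. Summed over each group, 368 counts against 2 gave a ratio of 247, with a 95% counting interval of 67.8 to 2044. Against PBS the rise was at least 95-fold, taking 3 counts over the PBS group as the floor. Library 4 held 256 of the 368 counts, and without it the ratio was 107 (29 to 895) and the bound 41.2-fold. Intervals and floors cover counting error only.

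All 4 Pdx1 gRNA libraries exceeded all 8 others in Pdx1 CPM. The exact two-sided permutation test gave p = 0.0286 against control gRNA and the same against PBS, the smallest value that the 70 assignments of 4 and 4 libraries allow. Adjusted over the 3 comparisons (Benjamini-Hochberg), both came to 0.0429, and control gRNA against PBS gave 1. In edgeR's quasi-likelihood test over all genes, the adjusted p against PBS was 0.00255. Since PBS had 0 counts, the fitted log2 fold change of 9.48 ± 1.48 (SE) rests on how the test treats 0, and it was 8.46 with DESeq2, 6.53 with limma-voom and 8.44 by edgeR without Pdx1 gRNA library 4, so only the lower bound is used. Against control gRNA it was 7.42 ± 1.11 with an adjusted p of 0.444, which did not pass 0.05 although Pdx1 ranked 1 of 15219 genes by rise and 2 by p-value. DESeq2 gave 7.78 with an adjusted p of 0.00613. Without Pdx1 gRNA library 4 edgeR gave 6.40 against control gRNA. Over the alternatives the adjusted p in that comparison ran from 0.00613 to 0.999, and the log2 fold change was positive in each.

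**Figure D2:**
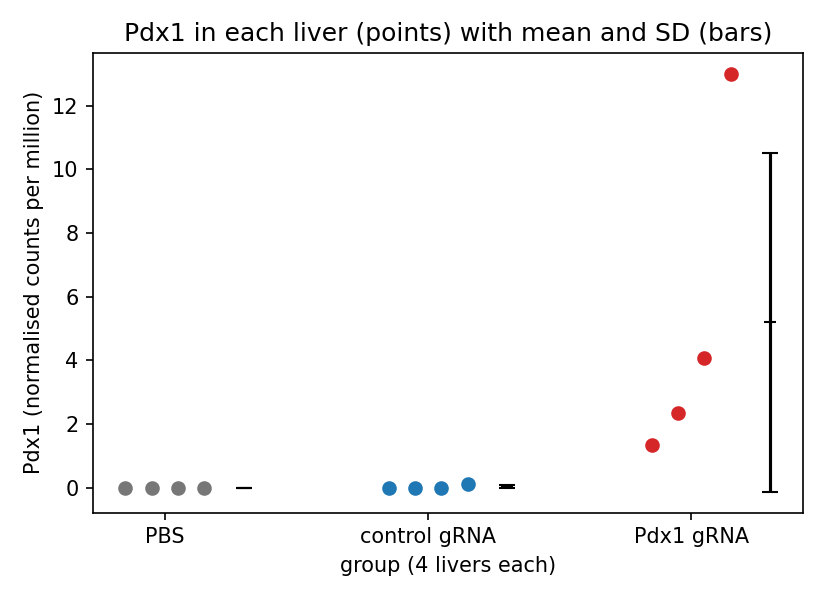
Pdx1 expression (y axis, CPM) in each of the 12 liver libraries (1 point per library) by group, with the group mean and SD. The 4 Pdx1 gRNA libraries lie between 1.35 and 13.0 CPM, and the PBS and control gRNA libraries lie at 0.111 CPM or below.

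Genes beside Pdx1 were read out to ask how far the effect of the gRNA reached. Among 31 annotated genes within 500 kb, 13 passed the filter, and Pdx1 was the only one called when p-values were adjusted over these genes alone (adjusted p = 7.6e-04, edgeR). Among the other 12, Urad, which encodes an enzyme of urate breakdown and lies 39.1 kb from Pdx1, had the smallest p, with 20.6 ± 9.80 against 12.0 ± 2.27 CPM (SD, n = 4) and an edgeR adjusted p of 0.536 among those 12. Its log2 fold change was 0.78 ± 0.35. Flt3 and Flt1, which encode receptor tyrosine kinases, had log2 fold changes of -0.76 ± 0.53 and -0.10 ± 0.28, and Usp12 had 0.38 ± 0.33. Log2 fold changes were 0.23 for Gtf3a, 0.22 for Rasl11a, 0.08 for Mtif3, -0.02 for Polr1d, -0.05 for Lnx2, -0.12 for Pan3, -0.19 for Rpl21 and -0.54 for Gm43461. The neighbouring homeobox genes Cdx2 and Gsx1 had 0 counts in both virus groups. Within 1 Mb, 20 of 52 genes were tested.

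Without the filter on low counts, 3 of the genes within 500 kb were called when adjusted over these alone. Besides Pdx1 they were Plut, which runs antisense to Pdx1 and overlaps its 5' part, with 17 counts after Pdx1 gRNA, 0 after control gRNA and 1 after PBS, and Gm27033, 4.87 kb away, with 15, 0 and 0. Both were named after their values were seen. Counting did not use strand, so reads of Pdx1 and Plut in their shared part cannot be assigned to a strand. Their edgeR adjusted p over these genes alone was 0.0104 for Plut and 0.0257 for Gm27033.

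Genes of the pancreas were read out in the same libraries. Of 31 pancreatic endocrine genes in the files, 9 had no count in any library, among them Ins1 and Ins2, which encode insulin, and Neurog3, and 2 passed the filter. Of 33 pancreatic exocrine and progenitor genes, 17 had no count in any library and 6 passed the filter. None of these 8 tested genes was called between Pdx1 gRNA and control gRNA, over all genes or adjusted over the list alone. Insm1, a zinc-finger gene of endocrine precursors, had 6 counts over the PBS group, 970 with the control gRNA and 677 with the Pdx1 gRNA. Its log2 fold change was 6.26 ± 2.25 for control gRNA against PBS (edgeR adjusted p = 0.0534) and -0.10 ± 1.45 between the virus groups. Of the 2 tested endocrine genes, 1 fell in control gRNA against PBS over all genes, and 1 rose and 1 fell adjusted over the list alone. Single libraries of Insm1 ran from 0.104 to 30 CPM with the control gRNA. Pdx1 gRNA libraries 1 to 4 had 0.673, 0.59, 0.302 and 33.1 CPM, so the value between the virus groups rests largely on library 4. Onecut1, a transcription factor gene of the liver and pancreas, fell by 1.82 on the log2 scale from PBS to control gRNA (edgeR adjusted p = 0.00907). Between the virus groups Onecut1 had a log2 fold change of 1.09 ± 0.44 (adjusted p = 0.809). The exocrine and progenitor list was not called in this comparison (camera, adjusted p = 0.104), nor in control gRNA against PBS (0.124), where 3 of 6 members fell over all genes and 4 adjusted over the list alone, nor in Pdx1 gRNA against PBS (0.338). With PBS libraries 2 and 3 left out, 2 members fell in control gRNA against PBS, and the median moved from -0.93 to -0.09. Amy1 and Nr5a2 held 10382 and 4570 of the 17226 counts of the exocrine and progenitor list after PBS. Its tested members thus include genes already expressed in the PBS livers.

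The comparison of Pdx1 gRNA with control gRNA asks what targeting added to the virus. No gene, Pdx1 included, passed the threshold of the test over all genes. Higher in all 4 Pdx1 gRNA libraries than in all 4 control gRNA libraries was Cry2, a repressor of the circadian clock, with 45.5 ± 4.41 against 28.2 ± 2.29 CPM (SD, n = 4). Lower in all 4 was Ifi27l2a, an interferon-stimulated gene, with 7.96 ± 1.16 against 19.4 ± 3.70 CPM. Cebpe, a transcription factor gene of granulocytes, had 1 count with the Pdx1 gRNA against 296 with the control gRNA, a ratio of 221 with a 95% counting interval of 39.3 to 8753. Its control gRNA libraries ran from 0.0414 to 7.37 CPM, so the groups overlapped.

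The edgeR test called 0 of 15219 genes between these groups, with 918 at an unadjusted p under 0.05, which unchanged genes reach at a rate of about 0.05. limma-voom also called 0 and DESeq2 called 14, with 6 higher and 8 lower. Log2 fold changes were 0.69 ± 0.11 for Cry2 (adjusted p = 0.444), 0.77 ± 0.16 for Gcn1l1, -1.28 ± 0.25 for Ifi27l2a, -1.51 ± 0.32 for AI662270 and -7.39 ± 1.51 for Cebpe, with adjusted p = 0.646 for Ifi27l2a and 0.65 for the other 3. DESeq2 called these 5 and Pdx1. In 1012 genes (6.65%) the 4 libraries of one group all lay above those of the other, where chance gives 2.86% on average. Genes move together across libraries, and neither this share nor the 918 was computed on other splits. Neither count therefore decides whether the groups differ. On simulated data for this comparison edgeR recovered 37 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, with 5 false calls, against 31 false calls by DESeq2. The simulated genes varied independently and 100 were changed by each fold, so these shares can overstate recovery in the real libraries. Leaving out Pdx1 gRNA replicate 4 gave 1 call, Gipc2, lower by a log2 fold change of -3.80 (adjusted p = 0.0454), a gene named after its value was seen.

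Gene lists were tested between the same groups. Of 27 tested lists 16 were called by camera, a number that 12 of 35 splits of the 8 libraries reached (highest other 20), so chance cannot be excluded for it. Interferon-stimulated genes were lower with the Pdx1 gRNA than with the control gRNA in all 40 members by sign, with a median log2 fold change of -0.62. No member was called over all genes, and 17 were lower when adjusted over the list alone. The list was called lower by camera (adjusted p = 1.1e-26) and kept its call with an estimated correlation (adjusted p = 0.0456), and fry, which does not compare a list with other genes, called it lower too (adjusted p = 0.0332), while without PBS libraries 2 and 3 in the fit the adjusted p with an estimated correlation was 0.0623. Ifit3, an interferon-induced antiviral gene, had 23 ± 4.62 against 40.9 ± 10.3 CPM (SD, n = 4). Neutrophil markers had a median of -1.77, and all 8 tested members were lower when adjusted over the list alone. S100a9, a calcium-binding protein gene of neutrophils, had 0.794 ± 0.501 against 3.06 ± 0.896 CPM. The camera call (adjusted p = 6.5e-10) held with an estimated correlation, with an adjusted p of 0.0456, but not without PBS libraries 2 and 3 in the fit (0.0623), and the fry adjusted p was 0.054. Circadian genes were higher, with a median of 0.50 and 2 members higher when adjusted over the list alone (camera, adjusted p = 1.3e-08). Their adjusted p was 0.0456 with an estimated correlation, 0.102 so without PBS libraries 2 and 3 in the fit, and 0.0642 with fry.

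The other lists called lower with the Pdx1 gRNA by camera had 0 members called over all genes and 0 adjusted over the list alone. T and NK cell markers had a median log2 fold change of -0.80 (camera adjusted p = 2.3e-12, and adjusted p = 0.27 with an estimated correlation). Macrophage, monocyte and dendritic cell markers had -0.83 (1.2e-13, and adjusted p = 0.27 with an estimated correlation). The stellate cell and fibroblast list had -0.68 (3.7e-10, and adjusted p = 0.27 with an estimated correlation). Antigen presentation and interferon-gamma genes had -0.39 (8.9e-11, and adjusted p = 0.373 with an estimated correlation). The cholangiocyte list had -0.53 (0.00593, and adjusted p = 0.51 with an estimated correlation), the sinusoidal endothelial list had -0.19 (0.0306, and adjusted p = 0.769 with an estimated correlation), and the mitochondrially encoded genes had -0.28 (0.0280, and adjusted p = 0.722 with an estimated correlation). Among their members, Cd8a of cytotoxic T cells had 1.13 ± 0.642 against 2.67 ± 0.897 CPM. The macrophage protease gene Ctss had 35.2 ± 15.7 against 75 ± 25.4 CPM, and the class II gene H2-Ab1 had 50.4 ± 19 against 86.6 ± 11.7 CPM.

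Hepatocyte and metabolic lists were called higher with the Pdx1 gRNA by camera, again with 0 members called over all genes and 0 adjusted over the list alone. Fatty acid synthesis genes had a median log2 fold change of 0.60 (camera adjusted p = 6.9e-09, and adjusted p = 0.274 with an estimated correlation). Cholesterol synthesis genes had 0.35 (1.3e-06, and adjusted p = 0.476 with an estimated correlation), and hepatocyte secreted and identity genes had 0.29 (6.4e-07, and adjusted p = 0.437 with an estimated correlation). Unfolded protein response genes had 0.17 (1.2e-05, and adjusted p = 0.27 with an estimated correlation), and gluconeogenesis and insulin-response genes had 0.19 (0.0111, and adjusted p = 0.476 with an estimated correlation). The male-biased liver genes had 0.72 (7.4e-04, and adjusted p = 0.51 with an estimated correlation), although both groups had the female pattern of Xist. Srebf1, which encodes a master regulator of lipid synthesis, had 237 ± 107 against 130 ± 36.7 CPM (SD, n = 4), with an edgeR adjusted p of 0.809. Of the 16 lists called, 7 were higher and 9 lower, and 3 held with an estimated correlation, none of these without PBS libraries 2 and 3 in the fit, and fry called 1.

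The remaining lists were not called between the virus groups. Median log2 fold changes were -0.28 for B and plasma cell markers, 0.10 for erythroid and blood genes, -0.16 for acute-phase genes, -0.21 for cell cycle genes, 0.31 for female-biased liver genes, 0.13 for PPAR alpha and fatty acid oxidation genes and 0.14 for drug and bile acid metabolism genes. Medians lay near 0 and had the opposite sign with upper-quartile factors for p53 and DNA damage genes (0.01), heat shock and immediate early genes (0.04) and the p300 and related acetyltransferase and bromodomain genes (0.02). For p53 and heat shock genes the mean had the sign opposite to the median, at -0.02 and -0.06, while camera's direction followed the median.

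Control gRNA against PBS asks what a virus whose gRNA was not aimed at Pdx1 changed, with any effect of the fusion included. Areg (ENSMUSG00000029378.5, chromosome 5, 91139599 to 91148432), a growth factor of the EGF family, rose from 0.281 ± 0.0991 to 55.3 ± 11.1 CPM (SD, n = 4). Nupr1 (ENSMUSG00000030717.9, chromosome 7, 126623249 to 126630861), a stress-induced chromatin protein gene, rose from 3.90 ± 2.02 to 380 ± 212 CPM. Ppara (ENSMUSG00000022383.13, chromosome 15, 85734983 to 85802819), which encodes the receptor that drives fatty acid oxidation, fell from 181 ± 71.9 to 27.9 ± 5.39 CPM.

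In total, 4887 of 15219 genes were called by edgeR, 2488 higher and 2399 lower, and 708 of them changed at least 4-fold. In 4388 genes (28.8%) the groups were fully separated, where chance gives 2.86%. With upper-quartile factors the split was 3001 higher and 1854 lower, and the median over all genes moved from -0.01 to 0.10, so directions of small changes are relative to the scaling. Without PBS libraries 2 and 3, 2258 genes were called, 1118 higher and 1140 lower, and with a covariate for Y-linked counts 2785 were called. Leaving out PBS library 1 alone gave 6875 calls, so the drop cannot be assigned to the Y-linked difference alone. Without PBS libraries 2 and 3, 14 cell cycle genes, 17 interferon-stimulated genes and 10 p53 and DNA damage genes were called higher. Called lower were 13 fatty acid synthesis genes, 10 gluconeogenesis and insulin-response genes and 4 hepatocyte genes. Heat shock and immediate early genes called higher then numbered 5, antigen presentation and interferon-gamma genes 2 and cholangiocyte genes 2, and 3 cholesterol synthesis and 4 drug and bile acid metabolism genes were called lower.

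Of 32 cell cycle genes, 28 rose and none fell over all genes, and 30 rose when adjusted over the list alone, with a median log2 fold change of 2.07 (camera adjusted p = 4.2e-15, and adjusted p = 0.213 with an estimated correlation). Cdk1, the kinase that starts mitosis, rose from 1.87 ± 1.29 to 12.3 ± 3.36 CPM, and Aurkb, a mitotic kinase gene, from 0.577 ± 0.486 to 5.0 ± 2.07 CPM (SD, n = 4). Of 25 p53 and DNA damage genes, 13 rose and 1 fell, and 14 and 1 did when adjusted over the list alone, with a median of 0.70 (3.1e-07, and adjusted p = 0.0771 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 6.03 ± 1.64 to 65.1 ± 18.2 CPM, and Eda2r, a death receptor gene, from 1.05 ± 0.344 to 6.91 ± 0.358 CPM. Of 26 heat shock and immediate early genes, 10 rose, as many as when adjusted over the list alone, with a median of 0.50 (7.4e-04, and adjusted p = 0.241 with an estimated correlation). Myc rose from 6.04 ± 3.73 to 57.1 ± 11.1 CPM and Jun from 21.8 ± 11.3 to 65.5 ± 13.9 CPM. Of 26 unfolded protein response genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.254), against 5 and 3 without PBS libraries 2 and 3. Its median was -0.09, its mean 0.48 and camera's direction up. The members that rose included Ddit3 and Trib3 of the integrated stress response, with log2 fold changes of 3.62 ± 0.24 and 3.77 ± 0.21.

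Of 40 interferon-stimulated genes, 29 rose and none fell, and 32 rose when adjusted over the list alone, with a median log2 fold change of 1.11 (camera adjusted p = 6.6e-13, and adjusted p = 0.204 with an estimated correlation). Usp18 rose from 12.2 ± 0.962 to 39.0 ± 3.10 CPM and Isg15 from 14.8 ± 4.95 to 49.7 ± 9.64 CPM (SD, n = 4). Of 39 antigen presentation and interferon-gamma genes, 18 rose (22 adjusted over the list alone), with a median of 0.79 (3.3e-06, and adjusted p = 0.604 with an estimated correlation), against 2 called without PBS libraries 2 and 3. Tgtp1, an interferon-inducible GTPase gene, rose by 2.63 ± 0.53 on the log2 scale. Markers of immune cells moved with these lists. Of 34 macrophage, monocyte and dendritic cell markers, 11 rose (12 adjusted over the list alone; median 1.05, camera adjusted p = 3.3e-04, and adjusted p = 0.604 with an estimated correlation). Of 32 T and NK cell markers, 3 rose, Cd8a, Cd8b1 and Pdcd1 (0 adjusted over the list alone; median 0.60, camera adjusted p = 0.0147, and adjusted p = 0.605 with an estimated correlation). When PBS libraries 2 and 3 were left out, T and NK cell markers had no call over all genes and an adjusted p of 0.181 as a list, and 1 macrophage, monocyte and dendritic cell marker was called. Gpnmb, a gene of lipid-laden macrophages, rose by 4.57 ± 0.65. Among B and plasma cell markers the immunoglobulin genes Ighg2b and Ighg2c rose, by 2.42 ± 0.55 and 2.96 ± 0.75, and so they did when adjusted over the list alone, while the list was not called (adjusted p = 0.449) and neither gene was called without PBS libraries 2 and 3 (adjusted p = 0.0516 for Ighg2b and 0.0797 for Ighg2c).

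Of 8 neutrophil markers 1 rose, Lcn2, which hepatocytes also express, over all genes and adjusted over the list alone (adjusted p = 0.111 without PBS libraries 2 and 3), and the list was not called (camera, adjusted p = 0.162). Of 16 cholangiocyte genes, 8 rose (9 adjusted over the list alone), with a median log2 fold change of 1.20 (camera adjusted p = 0.00568, and adjusted p = 0.604 with an estimated correlation), against 2 called without PBS libraries 2 and 3. Epcam, an epithelial adhesion gene, rose from 1.66 ± 0.737 to 7.33 ± 6.64 CPM, and Tm4sf4 from 140 ± 23.1 to 366 ± 40.9 CPM (SD, n = 4), of which Epcam was not called by edgeR without PBS libraries 2 and 3 (adjusted p = 0.11). Of 22 sinusoidal endothelial genes, 8 fell (9 adjusted over the list alone), with a median of -0.75 (3.8e-04, and adjusted p = 0.604 with an estimated correlation). Stab2, a scavenger receptor gene, fell from 86.2 ± 30 to 35.4 ± 8.43 CPM. Among 28 stellate cell and fibroblast genes Lum rose and Hgf and Reln fell, none did when adjusted over the list alone or without PBS libraries 2 and 3, and the list was not called (adjusted p = 0.812). Of 10 erythroid and blood genes 3 fell, Alas2, Hbb-bt and Hbb-bs, as many as when adjusted over the list alone, and the list was not called (adjusted p = 0.0823), while without PBS libraries 2 and 3 it was called lower (camera adjusted p = 0.00857, median -1.34, and adjusted p = 0.564 with an estimated correlation).

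Of 21 fatty acid synthesis genes, 18 fell and none rose, and 20 fell when adjusted over the list alone, with a median log2 fold change of -2.10 (camera adjusted p = 5.7e-10, and adjusted p = 0.241 with an estimated correlation). Srebf1 fell from 655 ± 191 to 130 ± 36.7 CPM, and Acly, which makes cytosolic acetyl-CoA, from 608 ± 304 to 142 ± 30.2 CPM (SD, n = 4). Of 24 cholesterol synthesis genes, 7 fell, as many as when adjusted over the list alone, with a median of -0.62 (0.00132, and adjusted p = 0.605 with an estimated correlation). Of 21 gluconeogenesis and insulin-response genes, 15 fell (17 adjusted over the list alone), with a median of -1.15 (1.2e-07, and adjusted p = 0.204 with an estimated correlation). The insulin receptor gene Insr fell from 181 ± 38.8 to 76.9 ± 5.01 CPM and G6pc, the last enzyme of glucose output, from 664 ± 349 to 152 ± 33.7 CPM. Of 36 hepatocyte secreted and identity genes, 23 fell (24 adjusted over the list alone), with a median of -0.80 (2.2e-07, and adjusted p = 0.445 with an estimated correlation). The fibrinogen gene Fgb fell from 4173 ± 710 to 1620 ± 229 CPM. Of 20 circadian genes, 9 fell, as many as when adjusted over the list alone, with a median of -0.58 (0.00238, and adjusted p = 0.241 with an estimated correlation). Cry2 fell from 55.9 ± 3.66 to 28.2 ± 2.29 CPM.

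Of 29 PPAR alpha and fatty acid oxidation genes, 4 rose and 8 fell, as many as when adjusted over the list alone, with a median log2 fold change of -0.50 (camera adjusted p = 0.0334, and adjusted p = 0.605 with an estimated correlation). Without PBS libraries 2 and 3, 2 rose and 4 fell and the list was not called (adjusted p = 0.213). Ppara and Cyp4a32 fell while Acot2, a mitochondrial thioesterase gene, rose from 11.2 ± 3.32 to 78.6 ± 26.4 CPM (SD, n = 4). Of 34 drug and bile acid metabolism genes, 9 rose and 15 fell (9 and 16 adjusted over the list alone), and the list was not called (adjusted p = 0.52). Its median was -0.81 and its mean -0.04. The glutathione S-transferase genes Gstm3 and Gsta1 rose from 76.0 ± 25.3 to 3318 ± 1429 CPM and from 1.51 ± 0.750 to 144 ± 63.4 CPM. These are members of multigene families whose near-identical copies can share reads, which makes the values of single members uncertain. Of 31 acute-phase genes, 2 rose and 7 fell, as many as when adjusted over the list alone, and the list was not called (adjusted p = 0.117, median -0.28), while without PBS libraries 2 and 3 none rose and it was called lower (camera adjusted p = 0.002, median -0.58, and adjusted p = 0.342 with an estimated correlation). The fibrinogen gene Fga fell by 1.56 ± 0.25 and the serum amyloid gene Saa4 by 1.56 ± 0.31 on the log2 scale.

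Male-biased liver genes fell in 13 of 16 tested members and in all 16 when adjusted over the list alone, with a median log2 fold change of -3.84 (camera adjusted p = 3.4e-05, and adjusted p = 0.569 with an estimated correlation). Without PBS libraries 2 and 3 the median was -1.10, no member was called and the list was not called (adjusted p = 0.127). Of 24 female-biased liver genes 1 fell, Sult3a1, and 0 when adjusted over the list alone (camera, adjusted p = 0.364). Their median was -0.38 and their mean -0.32 while camera's direction was up. Leaving out PBS libraries 2 and 3, the list was called lower (camera adjusted p = 0.0175, median -1.25, and adjusted p = 0.706 with an estimated correlation), with 3 members lower. Of the p300 and related genes, Kat2b and Ep300 fell and Kat2a rose, against 1 lower and 1 higher when adjusted over the list alone and none without PBS libraries 2 and 3, and the list was not called (adjusted p = 0.748). Ep300 (ENSMUSG00000055024.12, chromosome 15, 81585351 to 81652077), the mouse gene of p300, had 39.1 ± 2.51 CPM after control gRNA and 53.9 ± 8.29 CPM after PBS (SD, n = 4), a fall of 0.46 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0396) that was not called without PBS libraries 2 and 3 (adjusted p = 0.221). Mitochondrially encoded genes had a median of 0.01 and no call, with camera's direction down.

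Over the 27 tested lists, 16 were called between control gRNA and PBS, 8 in each direction, 0 held with an estimated correlation and 11 were called by fry. At least as many lists were called in 11 of 35 splits (highest other 21), so chance cannot be excluded for this number. Among named genes with a mean of at least 1 CPM, the largest rises were those of H19, Lhx1, Vmn2r3, Areg, Slc7a11, Akr1b7, Sh2d6, Tenm4, Wfdc3 and Gsta1. H19, an imprinted non-coding RNA of fetal liver, rose from 1.30 ± 1.12 to 973 ± 1718 CPM (SD, n = 4), with single libraries from 4.49 to 3539 CPM (edgeR adjusted p = 0.0226, and 0.134 without PBS libraries 2 and 3). Lhx1, a LIM-homeobox gene, had 0 counts in the PBS group and rose at least 46.2-fold against 3 counts over that group (adjusted p = 0.0439, and 0.141 without those libraries). Slc7a11, the cystine transporter gene, rose by 7.11 ± 2.37 on the log2 scale (adjusted p = 0.0407, and 0.165). Vmn2r3 (ENSMUSG00000091572.8, chromosome 3, 64258961 to 64287495), of the vomeronasal receptor family, rose from 0.0794 ± 0.0539 to 23 ± 5.57 CPM (adjusted p = 2.4e-06). Sh2d6 had 2 counts over the PBS group and 532 after control gRNA, a ratio of 154 with a 95% counting interval of 42.3 to 1272.

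The largest falls were those of Mup7, Serpina4-ps1, Hsd3b5, Ctse, Mup21, Slc22a28, Cnmd, Ugt3a1, Slc13a2 and Lrit2. Mup7 fell by 10.43 ± 2.35 and Hsd3b5 by 9.52 ± 2.05 on the log2 scale, with edgeR adjusted p = 0.0074 and 0.00594. Both belong to the male-biased list, and without PBS libraries 2 and 3 they had -1.35 and -3.13 (adjusted p = 0.305 and 0.0685). Mup21 fell by 6.68 ± 1.36, and by 3.38 without those libraries (adjusted p = 0.0293). The Mup genes are near-identical copies that can share reads. Ctse, which encodes cathepsin E, fell from 31.8 ± 30.3 to 0.156 ± 0.0831 CPM (SD, n = 4), and Cnmd, the gene of chondromodulin, from 6.85 ± 3.05 to 0.188 ± 0.0764 CPM. Both stayed called without PBS libraries 2 and 3, at adjusted p = 0.0086 and 0.0108.

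**Figure D3:**
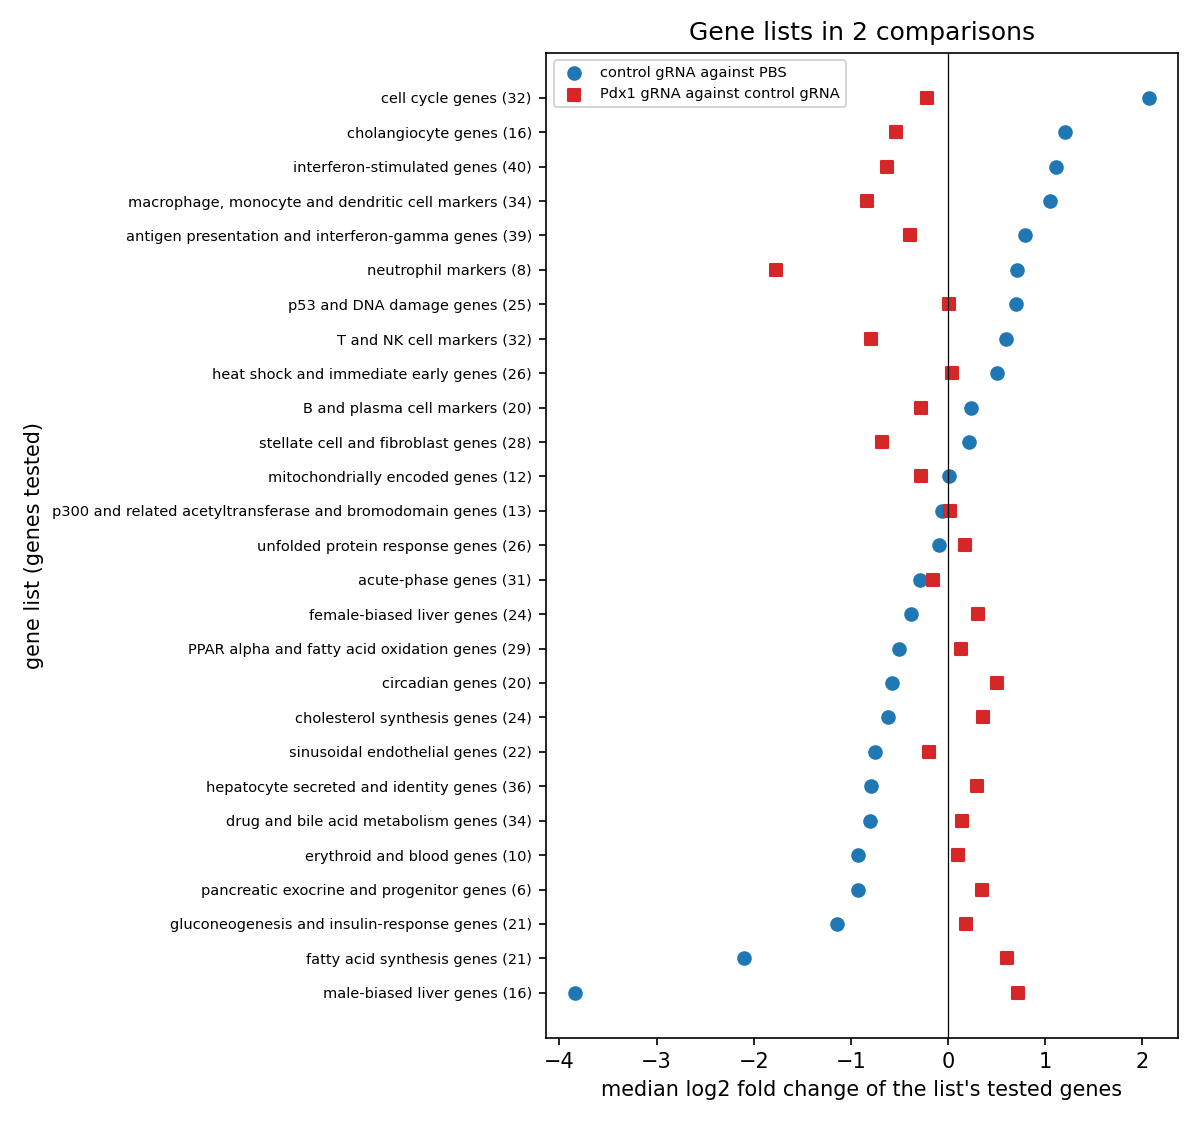
Median log2 fold change (x axis) of the tested genes of each of 27 gene lists (y axis, number of genes tested in brackets) for control gRNA against PBS (circles) and Pdx1 gRNA against control gRNA (squares). Cell cycle genes lie at 2.07 and fatty acid synthesis genes at -2.10 in the first comparison and neutrophil markers at -1.77 in the second, and since both share the control gRNA libraries with opposite sign, chance tends to set circles and squares on opposite sides of 0.

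Pdx1 gRNA against PBS holds any effects of the virus, of the fusion and of targeting together. Among named genes Pdx1, Vmn2r3, Tnfaip6, Areg and Sh2d6 had the largest rises and Cebpe, Ctse, Lrit2, Ppp1r3g and Lrit1 the largest falls, of which Lrit1 was not called without PBS libraries 2 and 3 (edgeR adjusted p = 0.0582). Areg rose from 0.281 ± 0.0991 to 57.6 ± 16.8 CPM and Vmn2r3 from 0.0794 ± 0.0539 to 22.5 ± 8.87 CPM (SD, n = 4), with edgeR adjusted p = 9.0e-08 and 1.9e-06. Tnfaip6, a hyaluronan-binding protein gene, rose from 0.117 ± 0.0858 to 29.0 ± 42.8 CPM, with 93.0 CPM in Pdx1 gRNA 4 and at most 12.3 in the others. Cebpe had 1 count against 486 in the PBS group, a ratio of 628 with a 95% counting interval of 112 to 24850. Ppp1r3g, a regulator of glycogen synthesis, fell from 13.9 ± 12.7 to 0.380 ± 0.150 CPM. Ep300 had a log2 fold change of -0.21 ± 0.16 (adjusted p = 0.362).

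In this comparison 3370 genes were called by edgeR, 1787 higher and 1583 lower. With PBS libraries 2 and 3 left out the count was 1277, 728 higher and 549 lower, and with the covariate for Y-linked counts 1795. It was 2132 without Pdx1 gRNA replicate 4 and 5421 without PBS replicate 1. Of the lists, 13 were called, 6 higher and 7 lower, 1 with an estimated correlation, fry called 7, and 17 of 35 splits gave at least 13 lists, so chance cannot be excluded for this number. The call with an estimated correlation was the p53 and DNA damage list, with 13 of 25 members higher and none lower (15 higher and 1 lower adjusted over the list alone), a median log2 fold change of 0.72 and an adjusted p of 7.2e-09 (adjusted p = 0.0392 with an estimated correlation, and 0.194 so without PBS libraries 2 and 3). Cell cycle genes rose in 26 of 32 members (31 adjusted over the list alone; median 1.88, adjusted p = 0.254 with an estimated correlation), and sinusoidal endothelial genes fell in 13 of 22 (16 adjusted over the list alone; median -1.0, adjusted p = 0.65 with an estimated correlation). Gluconeogenesis and insulin-response genes fell in 11 of 21 (16 adjusted over the list alone; median -1.01, adjusted p = 0.254 with an estimated correlation). Interferon-stimulated genes rose in 6 of 40 members (3 adjusted over the list alone; median 0.40, adjusted p = 0.664 with an estimated correlation). Fatty acid synthesis genes fell in 8 of 21 (11 adjusted over the list alone; median -1.15, adjusted p = 0.65 with an estimated correlation).

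Heat shock and immediate early genes rose in 8 of 26 members and none fell, against 10 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 2.3e-04, and adjusted p = 0.277 with an estimated correlation). Unfolded protein response genes rose in 8 of 26 and fell in 4, as many as adjusted over the list alone (median 0.04, adjusted p = 0.65 with an estimated correlation). Antigen presentation and interferon-gamma genes rose in 3 of 39, and in 2 adjusted over the list alone (median 0.31, adjusted p = 0.812 with an estimated correlation). Hepatocyte secreted and identity genes fell in 9 of 36 and rose in 1, against 11 and 1 adjusted over the list alone (median -0.50, adjusted p = 0.664 with an estimated correlation). Acute-phase genes fell in 9 of 31, as many as adjusted over the list alone (median -0.61, adjusted p = 0.664 with an estimated correlation), and stellate cell and fibroblast genes in 2 of 28, again as many (median -0.37, adjusted p = 0.78 with an estimated correlation). Male-biased liver genes fell in 7 of 16 members and in 10 adjusted over the list alone (median -2.37, adjusted p = 0.664 with an estimated correlation), and without PBS libraries 2 and 3 their median was -0.12, 1 member was called, higher, and the list was not called (adjusted p = 0.77). Members called without these libraries numbered 1 for interferon-stimulated genes and 0 for antigen presentation genes (list not called, adjusted p = 0.323) and hepatocyte genes. They were 11 higher for cell cycle, 4 higher for heat shock, and 6 higher and 1 lower for unfolded protein response genes, and 7 lower for sinusoidal endothelial, 5 for gluconeogenesis, 5 for acute-phase and 4 for fatty acid synthesis genes.

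The other lists were not called between Pdx1 gRNA and PBS. When PBS libraries 2 and 3 were left out, however, camera called neutrophil markers (adjusted p = 0.00467, median -1.76), erythroid and blood genes (0.0179, median -1.31) and cholesterol synthesis genes (0.0179, median -0.52) lower. With an estimated correlation none of these calls held (adjusted p = 0.523, 0.725 and 0.853). Members called higher over all genes numbered 7 of 34 for drug and bile acid metabolism genes, with 10 lower, 3 of 29 for PPAR alpha and fatty acid oxidation genes, with 4 lower, 3 of 16 for cholangiocyte genes, 2 of 20 for B and plasma cell markers, 2 of 13 for p300 and related genes, with 2 lower, and 1 of 34 for macrophage, monocyte and dendritic cell markers. Adjusted over the list alone the lower drug and bile acid metabolism genes numbered 13 and the other counts were the same. Cholesterol synthesis genes fell in 3 of 24 and erythroid genes in 1 of 10, and as many did when adjusted over the list alone. Leaving out PBS libraries 2 and 3 gave 5 higher and 0 lower for drug and bile acid metabolism genes, 2 and 1 for PPAR alpha genes, 2 higher for cholangiocyte genes and none for B and plasma cell markers, p300 and related genes, cholesterol synthesis genes and erythroid genes. It also gave 1 lower each for neutrophil markers, T and NK cell markers and female-biased genes. Median and mean differed in sign for T and NK cell markers (-0.17 and 0.01) and for drug and bile acid metabolism genes (-0.75 and 0.02). For B and plasma cell markers the median was -0.22 and the mean -0.03 while camera's direction was up, and down without PBS libraries 2 and 3.

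The virus groups were set against the same 4 PBS libraries, and 2938 genes were called in both comparisons in the same direction, 1572 higher and 1366 lower, with 0 called in opposite directions. These are 87.2% of the calls of Pdx1 gRNA against PBS and 60.1% of those of control gRNA against PBS. Independent lists of these sizes would share 292 higher and 250 lower genes, and unchanged groups simulated around shared PBS libraries shared 0.05 genes on average over 20 simulations. When the PBS libraries were split so that each comparison had its own 2, the overlap ran from 64 to 790 genes over the 6 splits. It was 1060 without PBS libraries 2 and 3. Any departure of the PBS libraries, such as the Y-linked counts of libraries 2 and 3, enters both comparisons. The overlap alone therefore does not measure a shared effect of the virus. Across genes, which are not independent replicates, log2 fold changes correlated with r = 0.91 against 0.526 in the simulation, and their covariance was 0.822 against 0.0845, a difference of 0.737. Areg is an example of these shared calls, 185-fold higher than in PBS with the control gRNA and 193-fold higher with the Pdx1 gRNA. The difference between the virus groups themselves is the comparison of Pdx1 gRNA with control gRNA, in which edgeR called 0 genes (918 at an unadjusted p under 0.05, 14 by DESeq2 and 0 by limma-voom).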

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

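The tests on PBS libraries 2 and 3, the removal of length and GC trends, the repeat without Mup genes and the counts by PBS library of genes on or off were chosen after the data were seen, as was the spread used for the immune marker test.

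For each named gene reported here and 6 library measures, the highest or lowest of the 4 libraries of a group was compared with the others, as its gap to the nearest library divided by the range of the group. In 42 of 429 groups (9.79%) this share was above the 95% critical value for 4 samples. Chance gives about 1 in 20 only for independent, normally distributed values. CPM of genes that move together are not such values, so the excess by itself does not show unusual libraries. The share is given in brackets. In PBS library 1 the highest values were those of Rpl21 (0.935), Gm43461 (0.943), Derl3 (0.906), Lcn2 (0.874), S100a8 (0.93) and Jun (0.925), and the lowest those of Amy1 (0.914) and Lrit1 (0.879). PBS library 2 was highest for Serpina1e (0.906) and lowest for Gbp6 (0.864), PBS library 3 highest for Srebf1 (0.896), and PBS library 4 highest for Akr1b7 (0.914) and Sh2d6 (1). Sh2d6 had counts in that PBS library alone. Control gRNA library 1 was highest for Spp1 (0.838), Lyve1 (0.906), H19 (0.904) and Ppp1r3g (0.884), with 3539 CPM of H19 against 4.49 to 342 CPM in the others. Control gRNA library 2 was lowest for Amy1 (0.899), and library 4 highest for Pdx1 (1) and Aacs (0.87), where the Pdx1 value is 2 counts against 0.

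Within its group, Pdx1 gRNA library 4 stood apart most often. It was highest for Cebpe (1), Usp12 (0.925), Flt3 (0.899), H19 (0.982), Lhx1 (0.923), Slc7a11 (0.988), Akr1b7 (0.958), Tenm4 (0.887), Wfdc3 (0.917), Gsta1 (0.951), Insm1 (0.989) and Tnfaip6 (0.911), and lowest for Slco1a1 (0.956), Hbb-bt (0.93), Hlf (0.902) and Kat2b (0.92). Slc7a11 had 123 CPM there against at most 1.55 in the others, Akr1b7 307 against at most 37.3, and Slco1a1 3.51 against at least 107. The Cebpe value is 1 count against 0. Pdx1 gRNA library 2 was highest for Lrit2 (1) and Lrit1 (0.923) and lowest for Ifit3 (0.902), and Pdx1 gRNA library 3 was highest for Slc13a2 (0.892) and Nr5a2 (0.894) and lowest for Gpnmb (0.853). Pdx1 gRNA library 4 differed less from control gRNA libraries 1 and 3 (chi-square per degree of freedom 43.0 and 39.6) than from its own group (88.4 to 111). Slc7a11 had 39.8 and 38.8 CPM in control gRNA libraries 1 and 3, and 4.64 and 7.87 CPM in 2 and 4. PBS library 1 differed less from Pdx1 gRNA libraries 1 to 3 (102 to 124) than from the other PBS libraries (139 to 177). Such differences thus cut across the groups, and no explanation was tested for them.

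Between control gRNA and PBS 4887 genes were called, and 1 of the 35 splits of these 8 libraries, the real one, gave as many (highest other 358). This is the smallest share that 35 splits can give, so chance is unlikely but not excluded. Without PBS libraries 2 and 3 the median ratio of the new to the first log2 fold change over these genes was 0.891 (quartiles 0.759 to 1.04), with 4878 in the same direction and 2046 still called, which argues against the Y-linked difference as the whole cause. With length and GC trends removed the ratio was 0.942 (quartiles 0.792 to 1.03), with 4881 in the same direction and 3909 still called, although the Spearman correlation of log2 fold change with length went from -0.206 to 0.000689, which argues against these trends as the whole cause. The male-biased liver genes went from a median of -3.84 to -1.10 without these PBS libraries, so a sex difference may account for most of their fall. An effect of the virus stays open, and since the source of Cre was not given, an effect of the dCas9-p300 fusion cannot be told apart from it. Batch, collection time and handling, which the labels do not give, stay open too.

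Interferon-stimulated genes were lower with the Pdx1 gRNA than with the control gRNA. Leaving out 1 library moved the median log2 fold change from -0.62 to between -0.77 and -0.52, which argues against a single library as the cause. The difference in mean log2 CPM over the 8 libraries was -0.63, and -0.38 with the mean of T and NK cell and macrophage markers in the model (-0.46 to -0.27 with each library left out). The markers were measured in the same libraries and were themselves lower with the Pdx1 gRNA. The model therefore cannot tell fewer immune cells from a change that lowered both the markers and the list. Fewer immune cells may account for part of the difference, and the 8 libraries do not decide whether or how much. An effect of the Pdx1 gRNA itself was not tested apart from fewer immune cells and stays open, as does any other difference between the virus groups. Against PBS, the median log2 fold change of the list was 1.11 with the control gRNA and 0.40 with the Pdx1 gRNA.

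In 49 autosomal genes, the libraries of at least 1 group were split into on (at least 1 CPM) and off (at most 0.1 CPM) with none between. They made 25 pairs within 2 Mb, against a median of 3 and a 95% bound of 7 in 10000 random sets (p = 1e-04 by permutation, the smallest they can give). Of these genes 42 were not Mup genes, and those made 4 pairs (median 2, bound 5, permutation p = 0.23). Linked strain variants may underlie such genes, but the excess rests on the Mup family, whose copies lie together and share reads, so these cannot be told apart here. Of the 33 genes that split the PBS group, 13 were on in PBS library 1 alone, and 5 were on in libraries 1 and 4 and off in 2 and 3, the libraries with Y-linked counts. A sex difference may underlie these 5. It cannot underlie the splits of 23 genes within a virus group, where all libraries had the female pattern. Apart from linked strain variants, no biological explanation was tested.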

How the results depend on the processing

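The PBS libraries 2 and 3 left out, the covariate for Y-linked counts and the length and GC trends were chosen after the data were seen, and the other alternatives before. Where a result changed, the cause was not tested unless stated. DESeq2 size factors left all 153 values of named genes on the same side of the threshold and in the same direction. The DESeq2 Wald test did so for 145 of 152 and called 7 more, no filter for 144 of 153, and the replicate block for 145 of 153. The length and GC trends did so for 149 of 153, the covariate for 130 and leaving out PBS libraries 2 and 3 for 125, with 27 calls lost there, where fewer libraries were tested. With 1 library left out, 1144 of 1224 values stayed, 66 calls were lost, 4 were gained and 10 values changed direction.

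Between Pdx1 gRNA and control gRNA, edgeR called 0 genes (918 at an unadjusted p under 0.05), limma-voom 0, DESeq2 14 with Pdx1 among them at a log2 fold change of 7.78, and edgeR on only the 8 libraries compared 1, Eif3j2. With 1 library left out it called 0 to 1, the 1 being without Pdx1 gRNA replicate 4. The Pdx1 log2 fold change ran from 6.40 to 9.47 and stayed uncalled (edgeR adjusted p from 0.137 to 0.999). Between control gRNA and PBS, where Pdx1 was not called, limma-voom gave -0.23 for Pdx1 (adjusted p = 0.911) against 2.06 in edgeR, a difference that rests on 2 counts, and without control gRNA replicate 4 it had no counts and so no value. With no filter, 3 genes near Pdx1 were called among these genes alone against 1, since more genes were tested. With the replicate block 0, 4127 and 2553 genes were called in the order Pdx1 gRNA against control gRNA, control gRNA against PBS and Pdx1 gRNA against PBS. The Pdx1 adjusted p in the first was 0.11.

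Leaving out 1 library gave 3445 to 6875 genes for control gRNA against PBS and 2132 (without Pdx1 gRNA replicate 4) to 5421 (without PBS replicate 1) for Pdx1 gRNA against PBS. Only the 8 libraries compared gave 2017 in the latter. A fold change threshold of 1.5 gave 1358 and 595, a stricter question by construction. Without PBS libraries 2 and 3 the counts were 2258 and 1277 and the overlap 1060, and with the covariate 2785 and 1795. The lists called with an estimated correlation were 3 of 16 for Pdx1 gRNA against control gRNA, 0 of 16 for control gRNA against PBS and 1 of 13 for Pdx1 gRNA against PBS, and fry called 1, 11 and 7. With the PBS libraries split, the overlap of 2938 came to 647, 790, 775, 64, 137 and 79 when PBS libraries 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4 went with the control gRNA, each fit having fewer libraries.

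Directions changed for uncalled genes near 0. Between Pdx1 gRNA and control gRNA with 1 library left out, log2 fold changes ran from -0.020 to 0.56 for Usp12, from -0.043 to 0.18 for Mtif3, from -0.18 to 0.077 for Lnx2, from -0.13 to 0.082 for Polr1d and from -0.27 to 0.076 for Flt1. Usp12 turned without Pdx1 gRNA replicate 4 and Mtif3 without replicate 3. With the length and GC trends removed, Ep300 had a log2 fold change of 0.079 in Pdx1 gRNA against PBS. Depth limits Pdx1 in the PBS and control gRNA groups, where at most 2 counts per group were seen. On simulated data edgeR recovered 37, 44 and 32 of 100 genes changed 2-fold in the 3 comparisons. The simulated genes varied independently and many were changed at once, so recovery in the real libraries can be lower. Uncalled changes of 2-fold are thus not excluded, nor are larger ones. Pdx1 itself stayed uncalled by edgeR between the virus groups at a log2 fold change of 7.42.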

Other observations

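The gene families below and Eif3j2, Gm3650, Gm43305 and Gipc2 were chosen after their values were seen, and the tests on other splits of the libraries were fixed before.

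Other splits of the libraries into groups of the same sizes were run for each count. Between Pdx1 gRNA and PBS, 1 of 35 splits, the real one, gave as many genes (3370, highest other 979). This is the smallest share that 35 splits can give, so chance is unlikely but not excluded. The test leaves the difference in Y-linked counts between these groups in place. Between Pdx1 gRNA and control gRNA, edgeR called 0 genes in the real split (highest other 1; 918 genes at an unadjusted p under 0.05, 14 by DESeq2, 0 by limma-voom), which all 35 of 35 splits reach by construction, so this count decides nothing. For the numbers of lists called chance cannot be excluded: 11 of 35 splits gave as many for control gRNA against PBS (16, highest other 21), 17 of 35 for Pdx1 gRNA against PBS (13, highest other 18) and 12 of 35 for Pdx1 gRNA against control gRNA (16, highest other 20). For the overlap of both comparisons with PBS, 1 of 100 drawn splits, the real one, gave as many genes (2938). The highest other, 2894, was a split that kept all 4 PBS libraries together, and draws that did not gave at most 1. The count thus depends on the PBS group staying whole. It cannot decide whether the grouping of the virus libraries matters.

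Of 87 genes picked by symbol as cytosolic ribosomal protein genes, 78 were called higher and 0 lower between control gRNA and PBS (edgeR). Their median log2 fold change was 1.12, between 1.09 and 1.22 under the other scalings. The symbols also took in Rps6kl1, a kinase-like gene (log2 fold change 1.69, called higher), and copies such as Rps3a2 and Rps3a3. The counts are thus not of ribosomal protein genes alone. Between Pdx1 gRNA and PBS 76 were higher (median 0.98), and without PBS libraries 2 and 3 the counts were 65 and 44. With the length and GC trends removed the control gRNA median was 0.99 and 74 genes were called higher. Of 23 genes picked by symbol as glutathione S-transferase genes, 13 were higher and 3 lower between control gRNA and PBS, with a median of 1.01. Between Pdx1 gRNA and PBS 8 and 3 were, with a median of 0.67, and none was lower in either without PBS libraries 2 and 3. Gstcd, named for a domain of these enzymes, was among the 23 and was called higher between control gRNA and PBS.

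Eif3j2 (chromosome 18, 43475418 to 43477796) had 25.3, 1.14, 1.02 and 0.93 CPM in PBS libraries 1 to 4, 16.5 to 20.7 CPM with the control gRNA and 1.51 to 2.06 CPM with the Pdx1 gRNA. On only the 8 virus libraries edgeR called it lower with the Pdx1 gRNA, at a log2 fold change of -3.30 (adjusted p = 3.0e-05). Gm3650 (chromosome 18, 43472816 to 43475169), beside it, had 4.32, 0, 0 and 0 CPM in PBS libraries 1 to 4, 1.64 to 2.65 CPM with the control gRNA and at most 0.155 CPM with the Pdx1 gRNA. Gm43305 (chromosome 14, 54292443 to 54297343) had 35 to 143 CPM after PBS, 4.51 to 298 CPM with the control gRNA and 2.19 to 8.8 CPM with the Pdx1 gRNA, and DESeq2 called it between the virus groups. Cebpe lies on the same chromosome (54710363 to 54712174). Control gRNA library 3 was the lowest of its group for both, with 4.51 CPM of Gm43305 and 0.0414 CPM of Cebpe. PBS library 3 was the lowest of its group for Gm43305 (35 CPM) and the highest for Cebpe (16.8 CPM). Gipc2 (chromosome 3) had at most 0.205 CPM after PBS, 6.73 to 23.7 CPM with the control gRNA, and 0.621, 1.4, 0.906 and 14.5 CPM in Pdx1 gRNA libraries 1 to 4.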
